A study of Arabidopsis thaliana with 3 samples.

How the data were processed

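RNA was sequenced from sorted Arabidopsis sperm cells with Smart-seq2, and the labels describe 3 sperm libraries from wild-type Col-0 plants. Nothing in the labels says whether the libraries came from separate plant cultures or sorts. The deposited table holds TPM values, in which the authors divided each transcript's estimated reads by its length and scaled every column to a fixed total of 1000000, as the unit named by the file implies. The submitters' processing notes name Trim Galore 0.4.1, STAR 2.5.2a, kallisto 0.43.1, SAMtools and bedtools and the TAIR10 build, without giving the role or order of each. Which transcript annotation was quantified, and any filter, are not given in the sources used here.

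The deposited table has 1 column for sperm, which sums to 1000000 over 33602 transcript identifiers, with 1 transcript per locus. Reads of another isoform of a locus could therefore be lost or assigned to the listed one. The column holds the authors' mean over libraries. This was checked on the digits of the 2424 values from 10 to 100 TPM. Multiplied by 3, 100.0% of them were whole multiples of 0.00001 TPM, within 0.03 of a step, against 33.4% after multiplication by 1, 2 or 4, as a mean of 3 numbers with 6 significant digits would give. The other 13 value columns name tissues that are not among the samples described here, and were not used.

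The comparisons planned before the data were examined assumed 1 value per library. They were moderated tests with limma that a gene lies above 1 TPM, a moderated test of each ratio and correlations between replicates. A column of means allows none of these, so levels, counts of genes and ratios are given as values with no SD, n or p. A mean at or above 1 TPM was used in place of the test. A mean can rest on 1 high library, and the digits of the means show this only in part, since a library at exactly 0, or one whose last digits are 0, leaves no trace. Of the 4089 means of 1 to 10 TPM, 527 (12.89%) carried digits that a library below 1 TPM would leave. Depth and counting error are unknown, since TPM keeps no counts, and no detection limit is given. A value of 0 is reported as listed at 0.

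Gene names came from a RefSeq table for assembly TAIR10.1, matched on locus tags, with 32835 of 33602 loci found and 10654 of them carrying a symbol. It was used for names and for gene order only, the order being taken from its chromosomes and start positions. Its coordinates were put to no other use, and no lengths were taken from it, because its assembly differs in name from the authors' build. The 17 gene lists held 208 distinct genes, all present in the table. For 180 the reference symbol or a synonym held the list's name, for 24 the reference gives no symbol, and 4 stand there under another name (HTR10 as MGH3, DMP9 as DAU2, BMI1B as DRIP1 and RALF19 as RALFL19). For the 24 without a symbol the reference could not check the name, which rests on the locus identifier alone. These include the H3 genes HTR1, HTR2, HTR3, HTR4, HTR5, HTR8, HTR9 and HTR13. They also include the H2B genes HTB5, HTB6, HTB7, HTB8 and HTB10 and the H3K27 demethylase gene JMJ13. In all, 0 were dropped. The lists covered the male germline, the vegetative cell and pollen tube, the tapetum, leaf photosynthesis, the egg cell, meiosis, Polycomb complexes, H3K27 demethylases, H3K4 and H3K27me1 methyltransferases, histones H3, H2A and H2B, histone chaperones, DNA methylation and small RNAs, replication and the cell cycle, sporophyte development and reference genes. The genes named were, by a rule fixed in advance, the 20 most abundant nuclear transcripts, up to 4 of the highest and 2 of the lowest members of each list and every gene in a ratio. Other list members and the groups in the closing section were named after their values were seen.

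Each list's median was placed among the medians of 10000 random lists of the same size drawn from all listed transcripts. Its percentile is the share of random medians below it, with tied random lists split evenly between lower and higher. This percentile describes 1 column and is not a test across replicates, and genes are not independent replicates. The calculation was run on simulated data. Of lists of 18 drawn from the 3000 most abundant of the 33602 transcripts, 20 of 20 passed the 97.5th percentile. Of random lists, 0 of 20 fell outside the central 95%. The first outcome was fixed in advance, since all 3000 were at or above 10 TPM. The 97.5th percentile of random medians for lists of 18 was 0.373 TPM. The simulation therefore checks the arithmetic only, and not lists at lower levels or of other sizes. The 8 ratios are differences of log2(sum of TPM + 1), or of the lists' median log2(TPM + 1) for the comparison of germline with vegetative lists. TPM compares genes only as far as the length correction holds, and reads of near-identical genes are divided by the estimation step. Alternatives were a threshold of 5 TPM, a pseudocount of 0.1, averaging members on the log2 scale, and rescaling without organellar genes or, chosen after seeing the data, without the 10 highest transcripts. One gene group is not reported here. Other pools for the random lists were also chosen after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.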

Results

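Transcript levels were measured by RNA sequencing in sperm cells of Arabidopsis thaliana, the pair of male gametes carried inside each pollen grain. The cells came from wild-type plants of the reference ecotype Col-0 and were isolated by fluorescence-activated sorting. Libraries were made with Smart-seq2, a low-input method that copies polyadenylated RNA into full-length cDNA. The labels describe 3 sperm libraries, and the table gives 1 value per transcript for them, the authors' mean in TPM, a length-corrected share of all transcripts scaled to the same total in every column. Values of the single libraries were not analysed here, so no value below carries an error, and no difference between genes was tested against the spread between replicates. The libraries' depth is unknown, because TPM keeps no read counts. The study's title concerns the histone mark H3K27me3 in paternal chromatin, and the genes described below were chosen around that subject and around the cell types that a sperm preparation could hold.

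The sperm transcriptome was dominated by a small number of transcripts. The most abundant was DAF1 (AT3G62230), named in the reference table as a DUO1-activated F-box gene, at 110116 TPM or 11.01% of the total. The 10 most abundant transcripts held 45.4% of all TPM, the top 20 held 55.5% and the top 100 held 73.8%. Of 33602 listed transcripts, 7281 (21.7%) were at or above 1 TPM, 768 at or above 100 TPM and 89 at or above 1000 TPM. A further 11841 lay between 0 and 1 TPM, and 14480 (43.1%) were listed at 0. Transcripts of the chloroplast genome summed to 78.6 TPM and those of the mitochondrial genome to 2777 TPM, together 0.29% of the total.

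**Figure D1:**
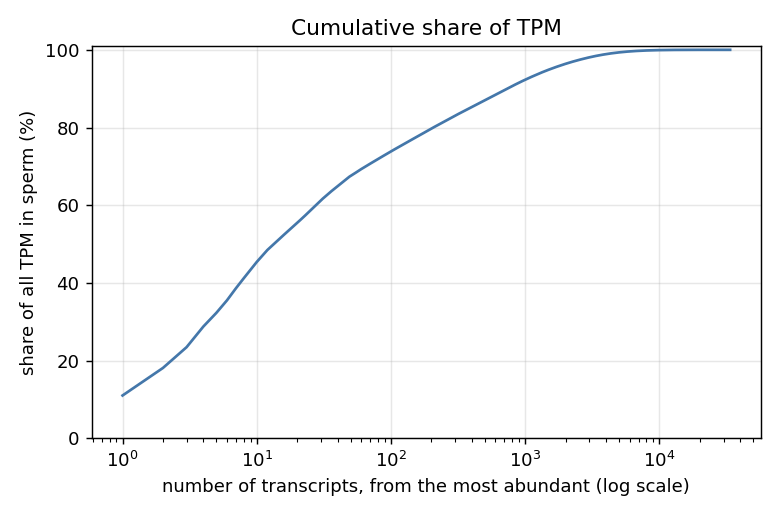
Cumulative share of all TPM in sperm (vertical axis, percent) against the number of transcripts counted from the most abundant (horizontal axis, log scale), from the authors' mean of the sperm libraries. The top 10 transcripts hold 45.4% and the top 1000 hold 92.3% of the total.

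Among the 20 most abundant nuclear transcripts, 4 belonged to gene lists fixed in advance. These were PCR11 (AT1G68610) at 16145 TPM, DAZ3 (AT4G35700) at 11141 TPM, the histone H2B gene HTB5 (AT2G37470) at 10019 TPM and the tonoplast intrinsic protein gene TIP5;1 (AT3G47440) at 9815 TPM. CYCD7;1 (AT5G02110), a D-type cyclin, was at 35229 TPM. DAN1 (AT3G04620), a DUO1-activated nucleic acid binding protein by its reference name, was at 7387 TPM, and AT4G37280, listed as MORF related gene 1, was at 8144 TPM. The ribosomal RNA gene AT3G41768 was at 8730 TPM. The others carry no symbol in the reference table. They were AT2G30230 at 70893 TPM, AT2G45403 at 53523 TPM, AT1G34095 at 53111 TPM, AT4G21895 at 32294 TPM, AT1G75870 at 31160 TPM, AT4G14315 at 25648 TPM, AT1G49290 at 22117 TPM, AT2G01021 at 19831 TPM, AT1G80470 at 14654 TPM, AT5G15030 at 7778 TPM and AT2G39420 at 6957 TPM.

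All 18 members of the male germline list were at or above 1 TPM, and 12 were at or above 100 TPM. The list median was 199.8 TPM. Besides PCR11, DAZ3 and TIP5;1, the highest member was HTR10 (AT1G19890), the male-gamete-specific histone H3, at 4750 TPM. GEX1, a gamete-expressed membrane protein gene needed for nuclear fusion, was at 1670 TPM, and DMP9, a sperm membrane protein gene, at 1342 TPM. SSP, whose paternal transcript acts in the zygote, was at 205 TPM. The gamete fusogen gene HAP2 was at 87.9 TPM and the adhesion gene GEX2 at 71.8 TPM. DUO1, the MYB transcription factor of the male germline, was at 82.3 TPM. The lowest members were DAZ2 at 39.4 TPM and DMP8 at 36.5 TPM. No random list of the same size, of 10000 drawn from all listed transcripts, had a median as high, which put this list at percentile 100. That place was easily reached, since the 97.5th percentile of random medians was 0.373 TPM. The vegetative cell and pollen tube list, described next, reached it too.

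Genes of the vegetative cell and pollen tube, the cell that encloses the sperm, were present at lower levels. Of the 24 members, 18 were at or above 1 TPM and 6 were below it, with a list median of 3.68 TPM. Only 9 members were at or above 5 TPM. The arabinogalactan protein genes AGP6 (127 TPM) and AGP11 (83.0 TPM), the pectin methylesterase gene VGD1 (78.9 TPM) and the signalling peptide gene RALF19 (38.3 TPM) were the highest. VEX1, a vegetative cell gene, was at 0.035 TPM and the MADS-box gene AGL66 at 0.186 TPM. The list stood at percentile 100 among random lists. The median log2(TPM + 1) of the germline list exceeded that of the vegetative list by 5.42.

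Markers of other tissues were near 0, with a few exceptions. Of the 5 egg cell genes, 4 (EC1.1, EC1.2, EC1.3 and EC1.4) were listed at 0 and EC1.5 was at 0.287 TPM. Of the 5 tapetum and anther wall regulators, A9, DYT1, AMS and TDF1 were listed at 0 and MS1 was at 0.022 TPM. Among 9 meiosis genes, SPO11-1, which encodes a subunit of the enzyme complex that makes meiotic DNA breaks, was the only one at or above 1 TPM, with 7.06 TPM. MSH4 was at 0.602 TPM, ZYP1A at 0.170 TPM and RCK at 0.117 TPM, while DMC1, SDS and SPO11-2 were listed at 0. Of the 10 leaf photosynthesis genes, 7 were below 1 TPM, including LHCA1 at 0.245 TPM, RCA at 0.010 TPM and LHCB2.1 listed at 0. The exceptions were the Rubisco small subunit genes RBCS3B at 795 TPM, RBCS1B at 29.1 TPM and RBCS2B at 7.01 TPM. These 3 genes are adjacent and near-identical copies, so the division of reads among them is uncertain. Their sum was 830.8 TPM.

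**Figure D2:**
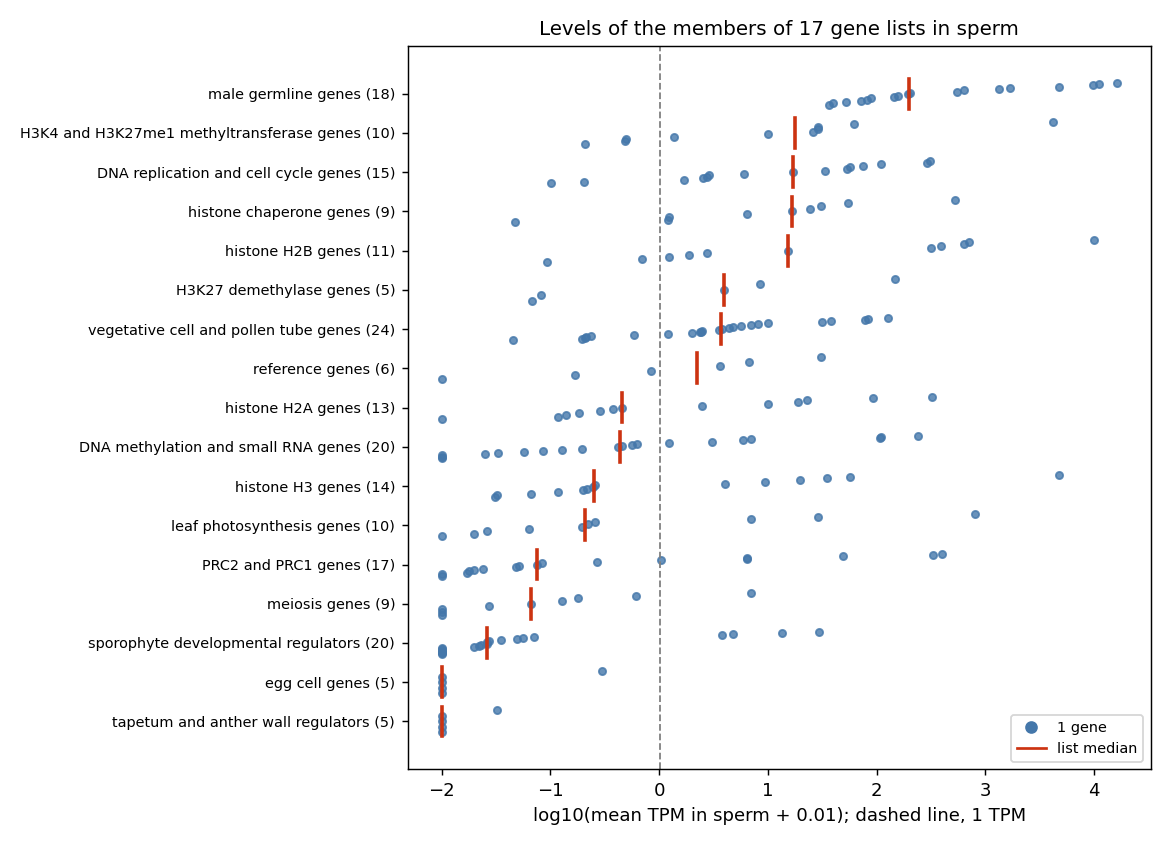
Levels in sperm of the members of 17 gene lists, as log10(mean TPM + 0.01) on the horizontal axis. Each point is 1 gene, red lines are list medians, the number of members is in brackets and the dashed line marks 1 TPM. The male germline list lies wholly above the line (median 199.8 TPM), and the egg cell and tapetum lists lie wholly below it.

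One comparison set the writers of H3K27me3 against its erasers. Of the 17 genes of Polycomb repressive complexes 2 and 1, 6 were at or above 1 TPM and 11 were below. The 3 genes for the H3K27 methyltransferase subunit of PRC2 were all low, with CLF at 0.065 TPM, SWN at 0.010 TPM and MEA at 0.008 TPM. FIS2 was at 0.007 TPM and EMF2 at 0.014 TPM, while VRN2, the other gene of that subunit family, was at 6.46 TPM. The shared subunit genes FIE and MSI1 were at 1.03 TPM and 6.43 TPM. The PRC1 RING finger genes BMI1B and BMI1A were at 398 TPM and 327 TPM, and VEL1, of the VIN3 family, was at 48.6 TPM. RING1B and EMF1 were listed at 0. Some genes used as expression standards in other tissues were also listed at or near 0, and the libraries' depth is unknown. Values this low therefore do not show that a transcript was absent.

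Of the 5 H3K27 demethylase genes, 3 were at or above 1 TPM. JMJ13 (AT5G46910) was at 147 TPM, REF6 at 8.39 TPM and ELF6 at 3.96 TPM. JMJ30 at 0.072 TPM and JMJ32 at 0.058 TPM were at levels like that of CLF. Summed TPM was 159.5 for JMJ13, REF6 and ELF6 together and 0.083 for CLF, SWN and MEA together, a log2 ratio of 7.21 after adding 1 TPM to each sum. JMJ13 gave most of the first sum, and JMJ30 and JMJ32 are not in it. With 0.1 TPM added instead, the log2 ratio was 9.77, and it was 4.21 when the genes of each side were averaged on the log2 scale.

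Methyltransferase genes for H3K4, H3K36 and monomethylation of H3K27 were mostly detected, with 7 of 10 at or above 1 TPM and a list median of 17.9 TPM. SDG4 (AT4G30860), also called ASHR3, was at 4187 TPM. SDG8 was at 61.4 TPM, ATXR6 at 28.8 TPM and ATX4 at 28.7 TPM. SDG2 was at 0.472 TPM and ATXR5, the second H3K27 monomethyltransferase gene, at 0.199 TPM. The list stood at percentile 100 among random lists.

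Histone RNA came mostly from a few genes. Of the 14 H3 genes 6 were at or above 1 TPM, and HTR10 made up 97.42% of their summed TPM. The 3 genes encoding the replacement variant H3.3, namely HTR4 (56.4 TPM), HTR8 (35.0 TPM) and HTR5 (19.8 TPM), summed to 111.2 TPM. The 5 genes encoding the replication-coupled H3.1 summed to 4.37 TPM, of which HTR1 gave 4.0 TPM. HTR2 was at 0.209 TPM, HTR9 at 0.108 TPM, HTR13 at 0.022 TPM and HTR3 at 0.021 TPM. The log2 ratio was 5.40 for HTR10 against H3.3 and 4.39 for H3.3 against H3.1. The first was 7.08 when the H3.3 genes were averaged on the log2 scale. That rise comes in part from the setting itself, since the average of 3 genes lies below their sum. Genes within the H3.1 and H3.3 groups encode near-identical proteins. If their reads are also hard to tell apart, which was not examined, the sums are firmer than the single values. HTR12, the centromeric H3, was at 9.38 TPM.

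Of the 11 H2B genes 9 were at or above 1 TPM, and HTB5 alone held 82.85% of the family's TPM. HTB7 was at 706 TPM, HTB8 (AT1G08170) at 642 TPM, HTB10 at 390 TPM and HTB6 at 315 TPM, and these 5 genes together held 99.82%. HTB2 was at 15.3 TPM, HTB9 at 2.77 TPM, HTB1 at 1.86 TPM, HTB4 at 1.22 TPM, HTB11 at 0.686 TPM and HTB3 at 0.083 TPM. The log2 ratio of HTB8 to the other H2B genes summed was -4.15, and it turned to 4.41 when the other genes were averaged on the log2 scale instead of summed. Among 13 H2A genes, 6 were at or above 1 TPM, led by HTA1 (322 TPM), HTA10 (92.3 TPM), the H2A.Z gene HTA11 (22.7 TPM) and the H2A.W gene HTA6 (19.0 TPM). The H2A.Z gene HTA8 was at 0.108 TPM and HTA4 was listed at 0.

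**Figure D3:**
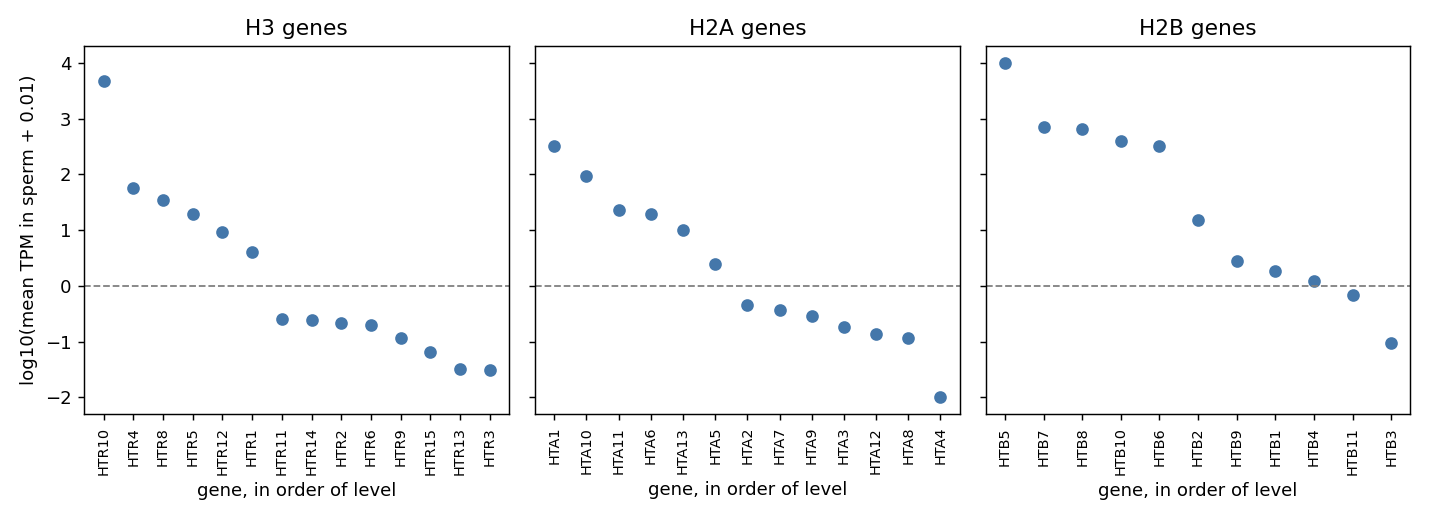
Levels in sperm of the H3, H2A and H2B genes, as log10(mean TPM + 0.01) on the vertical axis, with genes in order of level on the horizontal axis. Each point is 1 gene and the dashed line marks 1 TPM. HTR10 (4750 TPM) and HTB5 (10019 TPM) stand above all other members of their families.

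Of 9 histone chaperone genes, 8 were at or above 1 TPM. ATRX, a chromatin remodeller gene of the H3.3 deposition pathway, was at 525 TPM, ASF1B at 55.0 TPM, ASF1A at 30.8 TPM and FAS2 at 24.3 TPM. FAS1 was at 1.23 TPM and UBN2 at 1.19 TPM. HIRA, an H3.3 chaperone gene, was the exception at 0.037 TPM. The log2 ratio of HIRA to FAS1 and FAS2 summed, the large subunits of the CAF-1 chaperone for H3.1, was -4.67. It was -7.54 with 0.1 TPM added and -2.85 when FAS1 and FAS2 were averaged on the log2 scale.

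The 20 DNA methylation and small RNA genes were divided, with 7 at or above 1 TPM and 13 below. DDM1, a nucleosome remodeller gene, was at 240 TPM, MET1, the maintenance methyltransferase gene for CG sites, at 107 TPM and the Argonaute gene AGO9 at 109 TPM. AGO5 was at 7.05 TPM. CMT3, the CHG methyltransferase gene, was at 0.076 TPM, which gave a log2 ratio of 6.64 for MET1 against CMT3 with 1 TPM added and of 9.24 with 0.1 TPM added. CMT2, DML2 and NRPE1 were listed at 0. The DNA demethylase gene DME was at 0.015 TPM and ROS1 at 1.23 TPM, a log2 ratio of -1.13 with 1 TPM added and of -3.53 with 0.1 TPM added.

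Of 15 DNA replication and cell cycle genes, 13 were at or above 1 TPM, with a list median of 17.02 TPM. The replicative helicase genes MCM7 (309 TPM), MCM4 (109 TPM) and MCM3 (74.6 TPM) and the mitotic kinase gene CDKB2;2 (293 TPM) were highest. RBR1, the retinoblastoma homologue, was at 57.2 TPM. The lowest were FBL17 at 0.193 TPM and CDKA;1, the main cell cycle kinase gene, at 0.091 TPM. Sporophyte developmental regulators were mostly low, with 16 of 20 below 1 TPM and 6 listed at 0, among them WUS and STM. The 4 exceptions were BBM (29.8 TPM) and LEC1 (3.75 TPM), both regulators of embryo development, the flowering repressor gene FLC (13.6 TPM) and the zygotic patterning gene WOX2 (4.76 TPM). These counts do not set the list apart as low. Over all listed transcripts, 21.7% were at or above 1 TPM and 43.1% were listed at 0.

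Genes used as expression standards in other tissues were listed at varied levels. Whether their low values are true levels in sperm or missed RNA cannot be told here. UBC21 was at 30.6 TPM, UBQ10 at 6.63 TPM and SAND at 3.61 TPM. GAPC1 was at 0.840 TPM, TIP41-like at 0.159 TPM, and PP2AA3, which encodes a phosphatase subunit, was listed at 0. In all, 8 of the 17 lists had a median past the 97.5th percentile of random lists drawn from all listed transcripts, and 6 did when the random lists were drawn only from loci with a symbol in the reference table. The lists of histone H2B, histone chaperone and replication genes were at percentile 100, as were the germline, vegetative and H3K4 methyltransferase lists. The reference genes (3 of 6 at or above 1 TPM) were at percentile 96.0, the H2A genes at 96.7, the H3 genes at 92.4, leaf photosynthesis genes at 85.2, Polycomb genes at 75.0, meiosis genes at 67.3, sporophyte regulators at 41.7, egg cell genes at 18.5 and tapetum regulators at 18.2. These percentiles rest on the many transcripts listed at or near 0. The egg cell and tapetum lists had medians of 0 TPM, so no random list lay below them. Their percentiles of 18.5 and 18.2 came from tied random lists alone. With members and random lists restricted to transcripts above 0 TPM, the Polycomb genes were at percentile 3.9, sporophyte regulators at 0.1, meiosis genes at 21.3, leaf photosynthesis genes at 33.8, the H3 genes at 33.6, the H2A genes at 86.3, the DNA methylation and small RNA genes at 66.4, the H3K27 demethylase genes at 90.2 and the reference genes at 89.1. The egg cell list was then at 47.7 and the tapetum list at 12.5, each with 1 member left. The lists that lost their place past the 97.5th percentile among loci with a symbol were the H3K27 demethylase genes, from percentile 97.9 to 95.7, and the DNA methylation and small RNA genes, from 98.3 to 92.2.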

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

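The values describe 1 column of means, so no alternative could show the spread between libraries. At a threshold of 5 TPM, 4278 genes passed in place of 7281, with 9 in place of 18 vegetative cell and pollen tube genes and 2 in place of 4 sporophyte developmental regulators, and the counts of the other 15 lists stayed within 1.5 times. Rescaling without organellar genes kept all 18 counts and 8 ratios within 1.5 times. It multiplied the other levels by only 1.0029, so it could hardly have moved them and says little about how firm they are. Rescaling without the 10 highest transcripts, an alternative added after seeing the data, multiplied the other levels by 1.83. It moved the meiosis count from 1 to 2 and the log2 ratios of H3K27 demethylases to PRC2 methyltransferases to 7.99, of HIRA to CAF-1 to -5.48 and of MET1 to CMT3 to 7.43. A pseudocount of 0.1 gave log2 ratios of 9.77 for demethylases to PRC2 methyltransferases, -7.54 for HIRA to CAF-1, 9.24 for MET1 to CMT3 and -3.53 for DME to ROS1, each of which has a side below 0.1 TPM. Averaging members on the log2 scale gave 7.08 for HTR10 to H3.3, 4.21 for demethylases to PRC2 methyltransferases and -2.85 for HIRA to CAF-1. It reversed HTB8 to other H2B genes from -4.15 to 4.41, by its construction. In that ratio 1 gene is set against a sum and then against an average that the low members pull down. HTB7 alone, at 706 TPM, was above HTB8 at 642 TPM. The same construction enters HTR10 to H3.3 and HIRA to CAF-1, which also set 1 gene against several. Drawing random lists from loci with a symbol moved 9 of 17 list percentiles by over 5 points, and drawing them from transcripts above 0 TPM moved 11. The planned fits with and without trend or shrinkage, the rule that every library reach 1 TPM, leaving out each replicate and the correlations between replicates were not run, because they need values per library. The pseudocount and the filter at low values were not run for counts, since they act only on a test. Matching random lists on transcript length was not run, because no lengths of the build were used.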

Other observations

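Further groups were formed from the reference symbols after their values were seen, with no test of enrichment, and 21.7% of all listed transcripts were at or above 1 TPM. All 7 genes for the origin recognition complex were at or above 1 TPM, from ORC4 at 8.02 TPM to ORC6 at 5205 TPM. The CDK subunit genes CKS2 and CKS1 were at 3144 TPM and 203 TPM. TSO2, a small subunit gene of ribonucleotide reductase, was at 4069 TPM, while RNR1, the large subunit gene, was at 4.77 TPM. Of 40 cyclin genes, which include CYCB1;1 of the cell cycle list, 19 were at or above 1 TPM, and CYCD7;1 (35229 TPM) was followed by CYCB3;1 at 96.2 TPM. All 9 genes that the reference names as DUO1-activated were at or above 1 TPM, from DAU1 at 8.41 TPM to DAF1 at 110116 TPM. They include DAZ1, DAZ2, DAZ3 and DAU2 (DMP9) of the male germline list.

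Of 16 tetraspanin genes 4 were at or above 1 TPM, with TET12 at 547 TPM, TET11 at 195 TPM, TET7 at 38.7 TPM and TET16 at 5.23 TPM. TET11 and TET12 are also in the male germline list. Of 23 syntaxin genes 14 were, led by SYP72 at 515 TPM. Of 15 RNA polymerase II subunit genes, 12 were at or above 1 TPM, but NRPB2, the gene of the second-largest subunit, was at 0.056 TPM. Of the 89 transcripts at or above 1000 TPM, 87 could be placed on the 5 nuclear chromosomes of the reference table, and 17 of these (19.5%) had an adjacent gene at or above 100 TPM. The share was 6.6% among the 2408 of 2424 transcripts from 10 to 100 TPM that could be placed. The corresponding shares were 2.3% against 6.1% at 2 gene steps, 12.6% against 5.1% at 3, 5.7% against 5.0% at 4 and 6.9% against 5.2% at 5.

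All tests in this part were chosen after the values were seen, and with 1 group in the labels no biological explanation could be tested. The first pattern is RBCS3B at 795 TPM in cells without photosynthesis. RNA from green tissue would bring its other abundant transcripts. Of RBCS1A, LHCB1.1, LHCB1.3, LHCB2.1, LHCA1, RCA and PSBO1, the leaf list members outside the 3 adjacent Rubisco genes, the highest was at 0.245 TPM. These 7 genes were picked when their values were known, so this is a description and not a test. Their levels argue against RNA from green tissue. RBCS1B at 29.1 TPM and RBCS2B at 7.01 TPM were left out as near-identical copies of RBCS3B. RBCS3B took 95.7% of the TPM of the 3 adjacent Rubisco genes, and since the copies are near-identical, which of them the reads came from may differ from the estimate and cannot be told apart without the reads.

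The second pattern is the presence of pollen tube genes in sorted sperm, with 18 of 24 list members at or above 1 TPM. RNA carried over from the vegetative cell through the sort may account for it, and so may transcription in sperm. These cannot be told apart here, because a vegetative cell profile, which would fix the proportions that carry-over must have, was not used.

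The digits of the deposited means also bear on the libraries behind them, reported here as values only. If library values have 6 significant digits, a library above 0 but below 1 TPM usually leaves digits beyond the fifth decimal in 3 times the mean, though not where its last digits are 0 or cancel with those of another library. Of 4089 means of 1 to 10 TPM, 527 (12.89%) had such digits, so by this reading at least these include a library below the 1 TPM threshold, and 1 (0.02%) had digits beyond the sixth decimal. Of 2424 means of 10 to 100 TPM, 199 (8.21%) had digits beyond the fourth decimal and 0 beyond the fifth. A library at exactly 0 leaves no trace in the digits, so it stays open how many means rest on fewer than 3 libraries.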
